A study of Mus musculus with 4 samples.

How the data were processed

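Single-cell RNA sequencing was performed on glia-enriched suspensions of brain cells from male mice in which the mouse Apoe gene had been replaced by human APOE3 or APOE4. Mice received 5 mg/kg bacterial lipopolysaccharide (LPS) by intraperitoneal injection and were killed 24 h later, or received NaCl. Each of the 4 groups was represented by 1 library made from 3 mice, and nothing in the data assigned a cell to a mouse. Groups were taken from the sample titles. Libraries were made with 10x Genomics 3' chemistry with molecular identifiers and sequenced on an Illumina NovaSeq instrument, per the labels' protocols.

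The deposited files hold whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, which the authors made with Cell Ranger 7.0.1, per the file headers (version 7.0 and the mouse build mm10, per the submitters' processing notes). They hold 32285 genes, of which 78 share a symbol with another gene and were kept apart by identifier. Every deposited barcode had at least 500 UMIs, and no cell type annotation was used here. Counts aligned to a mouse genome do not measure the human transcript of a replaced locus in full, so the values of Apoe are those of sequence assigned to the mouse gene.

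Barcodes with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept. Of the barcodes, 93.3% passed in the APOE3 NaCl library, 93.7% in APOE3 LPS, 92.6% in APOE4 NaCl and 61.9% in APOE4 LPS, where 37.5% of barcodes held fewer than 1000 UMIs. Doublets were called per library with Scrublet in scanpy 1.11.5, with an expected rate of 0.8% per 1000 barcodes. It called 1391 barcodes (9.66%) in APOE3 NaCl, 1295 (8.60%) in APOE3 LPS and 1039 (7.95%) in APOE4 NaCl, and these were removed. In APOE4 LPS it called 0 of 18182 barcodes and so had not worked there. It was tried again on barcodes of at least 2000 UMIs (0 of 10133 called) and of at least 3000 UMIs (1082 of 7456, or 14.5%), and neither result was used. Called doublets were thus removed from 3 libraries and none from APOE4 LPS, and every comparison with that library carries this difference in treatment. In the other libraries fewer were called than the expected 11.5%, 12.05% and 10.5%, and cells with markers of another class remained in all 4 (21, 49, 18 and 73 astrocytes, 55, 22, 44 and 18 microglia and 78, 92, 68 and 109 endothelial cells, in the order APOE3 NaCl, APOE3 LPS, APOE4 NaCl and APOE4 LPS). An alternative that kept the doublets of all 4 libraries treats them alike.

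Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9) gave 34 clusters over the 4 libraries together, with no batch integration, because library and group cannot be told apart. Clusters were named from marker genes of 18 cell types. A marker counted when it was at least 2-fold above the other clusters and found in at least 25% of the cluster's cells, and a name needed 3 such markers, 33.3% of that type's markers, and no larger number of another type's markers among the 10 leading genes. The requirement for a share of the markers was added after a first version had named 2 clusters of low-UMI barcodes. A total of 4 clusters stayed without a name, 3 by that requirement and 1 because its leading genes held more markers of another type. They held 2.11% of cells in APOE3 NaCl, 4.40% in APOE3 LPS, 1.45% in APOE4 NaCl and 43.7% in APOE4 LPS. The remaining clusters formed 15 classes, here called astrocyte-like, microglia-like and so on, and below astrocytes, microglia and so on. Astrocytes, microglia and endothelial cells were compared between libraries.

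UMIs were summed per library and class and expressed as CPM of that class, which sets every class to the same total. Each ratio of a pair of libraries has an exact conditional binomial (Clopper-Pearson) 95% interval, each sum an exact Poisson 95% interval and each share of cells an exact binomial 95% interval. All cover counting error only, not variation between mice, library preparations or, for UMIs, cells. With 1 library per group no test was made. No p-value, standard error or number of significant genes is given, and no difference has a replicate check. Log2 values are of CPM + 1, which understates differences of genes near 0. A fold against 0 counts is a lower bound from a floor of 3 counts per library, and none is given when both libraries lie at or below that floor. For the difference of the LPS effect between genotypes an approximate counting interval was computed on the log scale.

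For each of 37 gene lists, the median log2 ratio of the measured members (at least 10 UMIs in 1 of the libraries compared) was set against 10000 random lists of the same size matched on mean expression in 20 bins, and members at least 1.5-fold higher or lower were counted. The percentile is a description of these libraries and not a test. Single genes are named by a rule on genes with at least 50 UMIs over the libraries compared and at least 20 CPM in 1 of them. Mitochondrial and ribosomal protein genes, unnamed gene models and genes under 10% of the CPM of another class, which free RNA can supply, were left out of it. Genes were ranked by the bound of the 95% interval nearest 1, taking the 10 highest and 10 lowest in astrocytes, 5 of each in microglia and endothelial cells, and 5 of each for the difference of LPS effects in astrocytes. Of each described list, the 2 members with the bound farthest from 1 are also eligible, without the limit on free RNA. Apoe, Gfap, Serpina3n, Lcn2, C3 and Xist are always eligible. A result that the rule would name is not reported here, and the counts of recomputed values leave it out.

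To compare astrocytes across depths, each cell was thinned to 1000 UMIs (5 draws), which left out 0 cells. The share of cells with a UMI, the Fano factor over genes with a mean of at least 0.1 UMI in every library and the correlation over 1000 pairs of cells were computed from thinned counts. Thinned counts of Igtp, Ifi47, Mt1 and Mt2 were added after their values had been seen, and of these only Mt1 is used, for the question of pooled mice.

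Procedures were tested on simulated counts of 14398 genes, 200 of them changed. These counts held counting error only and cannot show coverage in real cells. For LPS in APOE3, the intervals of 14198 unchanged genes covered the true ratio in 95.5%. They excluded 1 for 94% of genes changed 1.5-fold, 100% at 2-fold and 92% at 0.5-fold. For LPS in APOE4 the last 3 shares were 84%, 96% and 92%, and for genotype in LPS 86%, 96% and 90%.

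Groups, cell filters, marker genes, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives fixed then were lower and higher filters on cells, a 10% mitochondrial limit, doublets kept, Leiden resolution 2, TMM factors, CPM without mitochondrial and top 20 genes, the mean of each cell's CPM, a pseudocount of 10, measured genes from 50 UMIs or with no filter, possible free-RNA genes left out, and other settings of the thinning. A further 7 alternatives were chosen after seeing the data: single astrocyte clusters (2), astrocytes without 1 cluster, 1 unnamed cluster counted as microglia, free RNA subtracted, cells with markers of another class removed (at least 3 UMIs and over 0.5% of UMIs), and a floor of 200 UMIs for correlations. The minimum of 10 UMIs for the correlations across genes was also set then. Barcodes carried 1 suffix per library, so no split by suffix was possible. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9.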

Results

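The data describe the response of brain glia to systemic LPS, a bacterial endotoxin that provokes acute inflammation, in mice carrying human APOE3 or APOE4 in place of the mouse gene. APOE encodes the main lipid-carrying apolipoprotein of the brain, which astrocytes secrete, and the title of the series concerns the heterogeneity and the immunometabolic responses of APOE4 astrocytes. The 4 libraries, each pooled from 3 male mice, were APOE3 NaCl, APOE3 LPS, APOE4 NaCl and APOE4 LPS. They held 78513245 UMIs in 15432 barcodes, 114378032 in 16078, 73288965 in 14122 and 88460913 in 29361, in that order. The median barcode had 3969, 5640.5, 4236 and 1292 UMIs, so the APOE4 LPS library had the most barcodes and the shallowest. With 1 library per group there were no replicates, no difference was tested, and every interval below is a 95% interval of counting error.

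Astrocytes made up 32.1% of cells (95% interval 31.3 to 32.9) in APOE3 NaCl, 23.4% (22.7 to 24.1) in APOE3 LPS, 30.03% (29.2 to 30.9) in APOE4 NaCl and 12.5% (12.1 to 13.04) in APOE4 LPS. Microglia, the resident macrophages of the brain, made up 24.5%, 30.9%, 24.1% and 10.5%, oligodendrocytes 20.04%, 19.4%, 23.3% and 7.33%, and endothelial cells 6.56%, 5.94%, 5.03% and 2.21%, in the same order. Neutrophils, circulating phagocytes, were 0.0307% of cells in APOE3 NaCl, 0.828% in APOE3 LPS, 0.116% in APOE4 NaCl and 0.259% in APOE4 LPS. The shares depend on the glial enrichment, on depth and on the settings. In APOE4 LPS 43.7% of cells fell into clusters without a name, against 4.40% in APOE3 LPS, and they had a median of 1636 UMIs. With a filter of 2000 UMIs 37.4% had no name, against 5.95% in APOE3 LPS, and of these 3790 cells 2518 had none as analysed either, while 664 had been microglia. The astrocyte share in APOE4 LPS was 17.9% with that filter and 8.47% with filters of 200 genes and 500 UMIs, and at Leiden resolution 2 the astrocyte shares were 21.5%, 18.1%, 17.5% and 10.4%. The oligodendrocyte share in APOE4 LPS was 12.9% at 2000 UMIs and 4.36% with the lower filters. The endothelial share there was 7.16% at Leiden resolution 2 (5.203% in APOE4 NaCl), 7.09% with the lower filters (6.39%) and 5.07% at a 10% mitochondrial limit (5.18%). The neutrophil share in APOE4 LPS was 1.37% with the lower filters, against 0.838% in APOE3 LPS.

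The first question was what systemic LPS does to astrocytes of APOE3 mice. The comparison used 4179 astrocytes with 15128571 UMIs from the NaCl library and 3215 with 13127017 UMIs from the LPS library, most of them in the same pair of clusters (2 and 6). Fkbp5 (ENSMUSG00000024222), a co-chaperone of the glucocorticoid receptor, was 25.4-fold higher in the LPS library (20.7 to 31.4). Serpina3n (ENSMUSG00000021091), a secreted inhibitor of serine proteases, went from 13.2 to 269 CPM, 20.5-fold higher (17.8 to 23.7), and Plin4, a coat protein of lipid droplets, was 24.3-fold higher (17.1 to 35.8). Pla2g3, a secreted phospholipase, was 16.7-fold higher (11.8 to 24.2), the sulfotransferase Sult1a1 6.81-fold, the organic anion transporter Slco4a1 7.43-fold and Gpr179 6.42-fold. The transcriptional corepressor Hr was 5.57-fold higher, the elastic fibre protein Fbln5 5.32-fold and the sarcoglycan Sgcd 4.91-fold.

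Genes lower in APOE3 astrocytes after LPS were led by Rpe65 (ENSMUSG00000028174), an isomerase of retinoid metabolism, at 5.07-fold lower, and the dicarboxylate transporter Slc13a3 at 3.16-fold lower. The matrix proteoglycan Ncan was 2.83-fold lower, the zinc exporter Slc30a1 2.82-fold, the creatine-synthesis enzyme Gamt 2.84-fold, and the collagen gene Col23a1 2.79-fold, though it was near equal in cluster 6 alone (log2 0.025). The growth factor Ptn went from 2406 to 1039 CPM, 2.32-fold lower. The clock-controlled transcription factor Dbp, Hopx and the sarcosine oxidase Pipox were 2.29-fold, 2.29-fold and 2.40-fold lower. Gfap, the intermediate filament gene used as the standard marker of reactive astrocytes, was 1.89-fold higher (1.79 to 1.99). Lcn2, an iron-siderophore-binding acute-phase protein, had 3 UMIs in NaCl and 1532 in LPS, a ratio of 589 (201 to 2857), but its 117 CPM were 0.895% of those in another class of the same library. C3 had 48 UMIs in LPS, Apoe was near equal at 315 and 310 CPM, and Xist, expected near 0 in males, had 4 UMIs in each library.

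Among reactive astrocyte lists in APOE3, the pan-reactive list had a median log2 ratio of 1.05, with 9 of 12 measured members at least 1.5-fold higher, 2 lower, and a percentile of 100 among random lists (median 0.61 with a pseudocount of 10 and 1.86 in cluster 6). In the A1 list, genes associated with neuroinflammatory reactive astrocytes, 12 of 12 were higher (median 1.83). In the A2 list, genes associated with ischaemic reactive astrocytes, 3 of 8 were higher and 4 lower (median -0.40). That sign turned when doublets were kept (0.36), at Leiden resolution 2 (0.26), measured from 50 UMIs (0.60), with no low-count filter (0.16), in cluster 6 (0.75) and without cluster 7 (0.41), and Cd14 and Cd109, its highest members at 5.76-fold and 4.09-fold, were at 0.524% and 2.39% of another class's CPM. The disease-associated astrocyte list had 5 of 21 members higher (median 0.15), and the homeostatic list, transporters and channels of resting astrocytes, had 1 of 20 (median -0.08), with the gap-junction gene Gjb6 at 1.67-fold and Fgfr3 at 1.35-fold higher.

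Innate immune lists were also higher in the APOE3 LPS library. Of the interferon-stimulated genes 24 of 28 were at least 1.5-fold higher and 0 lower (median 1.01), including Ifi44 at 11.1-fold (4.82 to 31.6) and Ifitm3 at 5.18-fold. Of the MHC class I presentation genes 11 of 13 were higher (median 0.95), among them the transactivator Nlrc5 at 6.87-fold and H2-T23 at 6.29-fold. The NF-kB and acute-phase list had 10 of 21 higher (median 0.45) and the complement list 11 of 13 (median 1.69). Of the glucocorticoid-responsive genes 12 of 17 were higher (median 0.96), with Map3k6 at 61.9-fold (20.8 to 303) from 3 UMIs. A list of microglial transcripts that monitors RNA of other cells was higher in the same library too, with 7 of 9 members (median 0.94). Saa3 and the complement receptor C5ar1 in these lists stood at 0.0788% and 0.612% of another class's CPM.

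Of the metabolic lists, cholesterol synthesis had 0 of 24 members higher and 7 lower (median -0.46, percentile 0), with the mevalonate-pathway enzyme Mvd at 2.06-fold and the sterol sensor Insig1 at 1.83-fold lower. Glycolysis and lactate had 3 of 23 higher and 2 lower (median -0.14), with the glucose transporter Slc2a3 at 3.45-fold higher and enolase Eno1 at 1.79-fold lower. Nuclear genes of oxidative phosphorylation (OXPHOS) had a median of -0.13, with 1 of 77 lower and 0 higher.

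The second question was what LPS does in APOE4 astrocytes. The comparison used 3613 astrocytes with 14318563 UMIs from NaCl and 2281 with 9092970 UMIs from LPS, and 1 further cluster (7) joined clusters 2 and 6 in the LPS library. That cluster held 809 cells of APOE4 LPS, 193 of APOE3 LPS, 74 of APOE3 NaCl and 25 of APOE4 NaCl. It was led by Gfap, Gbp2, Iigp1, Mt2, Mt1, Serpina3n and Igtp, and may be the APOE4 LPS library rather than a type. Called doublets were removed from the other libraries and none from APOE4 LPS, here and in each comparison that uses it. Lcn2 (ENSMUSG00000026822) had 1 UMI in NaCl and 9242 in LPS (1016 CPM), a ratio of 14550 (2611 to 574900). Cxcl10 (ENSMUSG00000034855), an interferon-inducible chemokine, was 442-fold higher (214 to 1101), the interferon-inducible GTPases Iigp1 295-fold (135 to 805) and Ifi47 335-fold (59.6 to 13310), and the guanylate-binding protein Gbp2 (ENSMUSG00000028270) 232-fold (129 to 465). The small heat-shock protein Hspb1 was 112-fold higher (77.2 to 169), Gbp5 47.4-fold, the inhibitory Fc receptor Fcgr2b 57.3-fold, the kinase Map3k6 71.9-fold and Fkbp5 34.2-fold (27.7 to 42.6). Gfap was 8.21-fold higher (7.57 to 8.92), Serpina3n 12.2-fold (11.3 to 13.3) and C3 17.9-fold from 3 UMIs (5.61 to 90.8).

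Genes lower in APOE4 astrocytes after LPS were again led by Rpe65, at 8.51-fold lower, followed by the collagen gene Col11a2 at 4.09-fold, the Notch target Hes5 at 3.25-fold, Tagln3 at 3.25-fold and the orphan receptor Gpr158 at 3.35-fold. The peptide ligand Apln was 2.96-fold lower, Gamt 2.93-fold, Ncan 2.54-fold, Tst, a mitochondrial sulfurtransferase, 2.44-fold and Ptn 2.41-fold. Apoe counts were 1.18-fold lower (1.12 to 1.25) and Xist had 1 UMI in each library.

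All 13 measured pan-reactive genes were at least 1.5-fold higher in APOE4 LPS (median log2 3.36, and 1.54 without cluster 7), as were 12 of 12 A1 genes (3.71) and 10 of 10 A2 genes (2.74), among them the sphingosine kinase Sphk1 at least 42.0-fold and Slc10a6 at 176-fold (31.0 to 7027). The disease-associated astrocyte list had 7 of 21 higher (0.19). Homeostatic genes had 1 of 20 higher and 2 lower (-0.16), with the amino acid transporter Slc7a10 at 1.83-fold and the BMP antagonist Chrdl1 at 1.94-fold lower, though Chrdl1 was higher in cluster 6 alone (log2 0.52). Interferon-stimulated genes were higher in 28 of 28 (2.66), with Oasl2 at 38.2-fold and Ifi44 at 49.1-fold, and MHC class I genes in 13 of 13 (2.34), with H2-T23 at 35.8-fold and H2-Q4 at 38.0-fold. The NF-kB and acute-phase list had 18 of 21 higher (1.29), with Bcl3 at 59.2-fold, and complement 13 of 14 (1.82), with C1ra at 68.5-fold from 2 UMIs (18.4 to 575) and Serping1 at 59.8-fold. Glucocorticoid-responsive genes were higher in 13 of 17 (0.74). The monitor list of microglial transcripts was higher in 8 of 9 (median 1.97) in the same comparison.

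Cholesterol synthesis genes were lower in APOE4 as well, with 9 of 24 at least 1.5-fold lower and 0 higher (median -0.50), led by Mvd at 2.18-fold and the sterol reductase Tm7sf2 at 2.01-fold lower. Glycolysis and lactate had 3 of 23 higher and 2 lower (-0.19), with hexokinase Hk2 at 3.93-fold and Slc2a3 at 3.17-fold higher, and nuclear OXPHOS genes had 3 of 78 lower and 1 higher (-0.21). In the list for metallothioneins and oxidative stress 6 of 17 were higher (0.33), among them Txnip, an inhibitor of thioredoxin, at 5.00-fold and the metal-binding Mt2 at 3.30-fold, although Mt2 was near equal in cluster 2 alone (log2 -0.067). In APOE3 the same list had a median of 0.00, with Txnip at 3.098-fold and Mt1 at 1.41-fold higher.

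**Figure D1:**
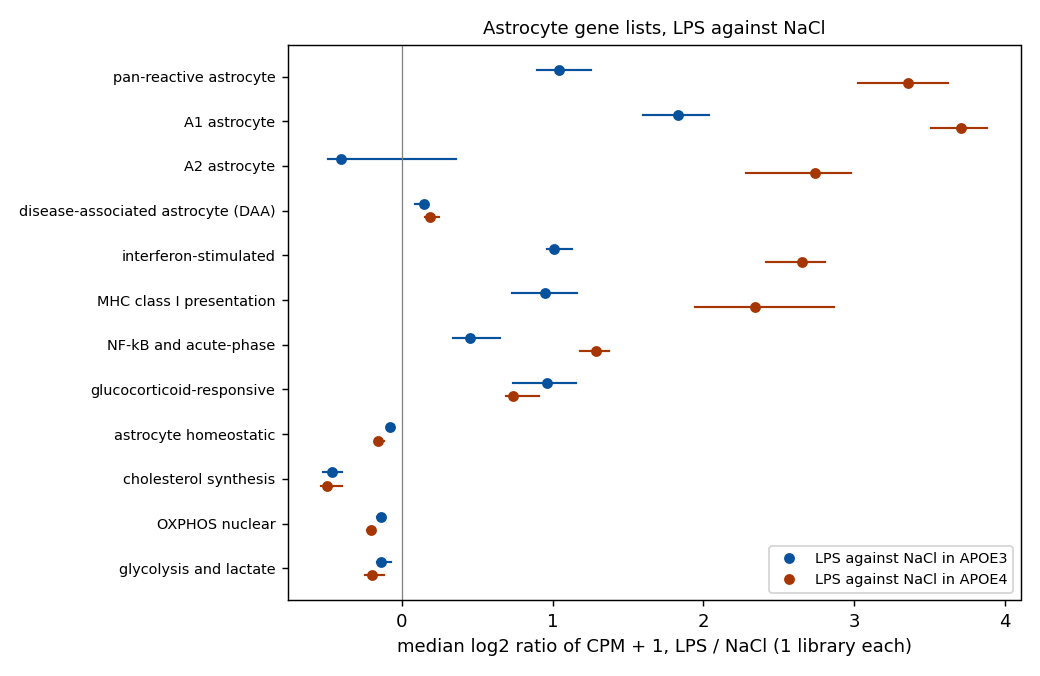
Median log2 ratio of CPM + 1 (LPS over NaCl) of 12 gene lists in astrocytes, with APOE3 in blue and APOE4 in red; lines are 95% intervals from redrawing the counts and cover counting error only. The pan-reactive, A1, A2, interferon and MHC class I lists lie farther to the right in APOE4 (3.36 against 1.05 for the pan-reactive list), while cholesterol synthesis lies below 0 in both (-0.46 and -0.50).

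A direct question of the design is whether the response to LPS differs by genotype, here the log2 LPS/NaCl ratio of APOE4 minus that of APOE3. In astrocytes the difference was 2.10 for the pan-reactive list (12 of 13 members higher by at least 1.5-fold, 1 lower) and 1.48 for interferon-stimulated genes (23 of 28 higher, 0 lower). By gene it was 5.37 for Gbp2 (4.37 to 6.37), 5.01 for Hspb1 (4.35 to 5.66), 4.23 for Cd44, a hyaluronan receptor (3.60 to 4.86), 3.86 for Gbp5 (2.78 to 4.93) and 3.03 for Igtp (ENSMUSG00000078853), an interferon-inducible GTPase (2.52 to 3.53). Differences in the other direction were -1.88 for Pla2g3 (-2.60 to -1.16), -0.89 for the glutamate receptor subunit Grin2c, -0.89 for Psd2, -1.15 for Col11a2 and -1.10 for the sodium-calcium-potassium exchanger Slc24a4. It was 2.10 for Gfap (1.96 to 2.24), -0.67 for Serpina3n (-0.91 to -0.43), -0.22 for Apoe (-0.31 to -0.12), 3.28 for Lcn2 with a wide interval (0.0092 to 6.54), and 0.01 for C3 (-2.38 to 2.41).

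In the alternative without cluster 7, that cluster was left out of all 4 libraries, including its 193 cells of APOE3 LPS. It is defined partly by these genes. The pan-reactive difference was then 0.15 (-0.00065 in cluster 2, 0.069 in cluster 6) and the interferon difference 0.064 (-0.40 and 0.32). By gene it was then -0.42 for Cd44, 1.49 for Gbp2, 0.92 for Hspb1, 0.54 for Gbp5, 0.40 for Igtp, 0.013 for Gfap (0.24 in cluster 2, -0.59 in cluster 6), -0.19 for Lcn2 (-0.21 and -0.12) and -2.78 for Serpina3n.

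Between genotypes without LPS, APOE4 NaCl astrocytes had more Serpina3n than APOE3 NaCl astrocytes, at 48.1 against 13.2 CPM, 3.65-fold (3.12 to 4.30), and less Gfap, at 48.2 against 151 CPM, 3.14-fold lower. Rpe65 was 1.75-fold higher, the Y-linked translation factor gene Eif2s3y (ENSMUSG00000069049) 1.54-fold, Kirrel2 1.63-fold, the glycogen-targeting phosphatase subunit Ppp1r3g 1.47-fold, the laminin chain Lama3 1.53-fold, Prelp 1.45-fold, Naaa 1.42-fold, the isoprenoid enzyme Idi1 1.39-fold and the complex I subunit Ndufa3 1.36-fold. Lower in APOE4 were Col23a1 at 1.91-fold, Nat8f5 at 1.87-fold, Fbln5 at 1.83-fold, Nbas at 1.58-fold, the homeobox gene Six3 at 1.70-fold, the inositol transporter Slc5a3 at 1.56-fold, the ephrin Efna5 at 1.504-fold, the calcium channel Cacna1a at 1.54-fold and the transcription factor Sox9 at 1.34-fold. Apoe counts were 1.13-fold lower. Lcn2, C3 and Xist had 1 to 4 UMIs per library. The log2 ratio of Col23a1 turned to 0.028 with doublets kept, 0.0087 in cluster 2, 0.12 in cluster 6 and 0.063 without cluster 7, that of Fbln5 to 0.014 in cluster 2, and those of Naaa and Ppp1r3g to -0.055 and -0.034 in cluster 6.

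The pan-reactive list was lower in APOE4 NaCl, with 7 of 11 members lower and 1 higher (median -0.99, percentile 0), among them Timp1 at 36.9-fold lower from 1 UMI against 39, and Cxcl10 at 12.3-fold lower. The A1 list had 5 of 11 lower (-0.52), with Iigp1 at 5.36-fold and Gbp2 at 3.61-fold lower, and the A2 list 5 of 8 lower and 1 higher (-0.61), with Clcf1 at 4.26-fold and S100a10 at 1.53-fold lower. Interferon-stimulated genes had 4 of 25 lower (-0.25), with Oasl2 at 3.04-fold and Ifit1 at 2.01-fold lower. All of these members stood at 1.02% to 6.95% of another class's CPM. The pan-reactive median was -0.32 with a pseudocount of 10, -0.36 in cluster 2 and -0.11 without cluster 7. In cluster 6 alone it was 0.16, the A2 median 0.066 (-0.079 without cluster 7), the A1 median -0.087, and the log2 ratio of S100a10 0.047 and of Gfap 0.078, against -1.63 for Gfap over all astrocytes. MHC class I (-0.05), NF-kB (-0.06), disease-associated (-0.03), homeostatic (0.02), glucocorticoid (-0.01) and glycolysis lists (0.04) were near 0. Stat3 was 1.38-fold lower and Klf9 1.198-fold lower, Psmb8 was 1.68-fold lower, H2-K1 was 1.04-fold higher and Sod2 1.07-fold higher, the potassium channel Kcnj10 was 1.27-fold lower and Chrdl1 1.33-fold higher, and Ldhb and Aldoc of glycolysis were 1.21-fold and 1.14-fold higher. Cholesterol synthesis (median 0.25, 0 of 24 past 1.5-fold, percentile 100) and nuclear OXPHOS (0.11, 2 of 78 higher and 1 lower) were slightly higher in APOE4, with Hmgcs1 at 1.29-fold.

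After LPS, astrocytes of the APOE4 library had more interferon-inducible and reactive transcripts than those of the APOE3 library. Ptx3 (ENSMUSG00000027832), a secreted pattern-recognition protein, was 64.2-fold higher (29.1 to 177), Ifi47 51.3-fold (23.2 to 141), Iigp1 26.2-fold (20.2 to 34.3), Gbp2 21.6-fold (17.8 to 26.5) and Cxcl10 21.0-fold (17.7 to 25.2). Hspb1 was 15.8-fold higher (13.6 to 18.5), Gbp5 11.8-fold, the stress-response gene Gadd45b 9.40-fold, Lcn2 8.71-fold (8.25 to 9.20) and H2-Q4 8.22-fold. Serpina3n was 2.18-fold (2.09 to 2.28) and Gfap 1.39-fold higher (1.32 to 1.45). Lower in APOE4 were Pla2g3 at 3.34-fold, Crym, a thyroid hormone-binding protein, at 1.997-fold, the guanine exchange factor Psd2 at 1.83-fold, the apolipoprotein Apoc1 at 1.82-fold, Aifm3 at 1.74-fold, the histamine receptor Hrh1 and Slc24a4 at 1.71-fold each, Nbas at 1.63-fold, angiotensinogen (Agt) at 1.60-fold and the adhesion receptor Adgrg1 at 1.59-fold. Apoe counts were 1.31-fold lower (1.24 to 1.38), and C3 was near equal (1.02-fold, 0.639 to 1.62). Crym turned to higher (log2 0.74) at Leiden resolution 2.

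By list, the pan-reactive genes were higher in 11 of 13 (median 1.12), A1 in 9 of 12 (0.89) and A2 in 10 of 10 (2.17), with Tgm1 at 41.9-fold from 2 UMIs (11.1 to 354). Interferon-stimulated genes were higher in 23 of 28 (1.28), with Igtp at 6.89-fold and Isg15 at 5.41-fold, MHC class I in 12 of 13 (1.35), with H2-T23 at 6.62-fold, and NF-kB in 11 of 21 (0.73), with Bcl3 at 6.31-fold and Saa3, an acute-phase apolipoprotein at 0.862% of another class's CPM, at 9.56-fold. The glucocorticoid list had 4 of 17 higher (0.13), with Map3k6 at 2.46-fold, and the disease-associated list 4 of 21 higher and 1 lower (0.18). Homeostatic genes had a median of -0.11 with 0 of 20 past 1.5-fold, among them Fgfr3 at 1.34-fold and Slc7a10 at 1.35-fold lower. Cholesterol synthesis was at 0.25 with 0 of 24 past 1.5-fold, led by Msmo1 at 1.45-fold and Insig1 at 1.43-fold, nuclear OXPHOS at 0.07 and glycolysis at -0.04, where the monocarboxylate transporter Slc16a1 was 2.47-fold and Hk2 1.76-fold higher.

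The pan-reactive median was 2.48 measured from 50 UMIs and 2.52 with possible free-RNA genes left out. Outside cluster 7 much of this turned. The log2 ratio of the pan-reactive list was 0.24 without cluster 7, 0.42 in cluster 6 and -0.36 in cluster 2, that of interferon-stimulated genes -0.091 without cluster 7 and -0.46 in cluster 2, and that of MHC class I genes -0.058 and -0.21. Without cluster 7, Gfap was at -0.80, Lcn2 at -0.19, Serpina3n at -0.26, Map3k6 at -0.41, the glucocorticoid list at -0.15 and the disease-associated list at -0.038. In cluster 2, A1 genes were at -0.080, NF-kB genes at -0.16, Bcl3 at -1.13, Isg15 at -0.64, Hk2 at -0.50 and Msmo1 at -0.023.

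**Figure D2:**
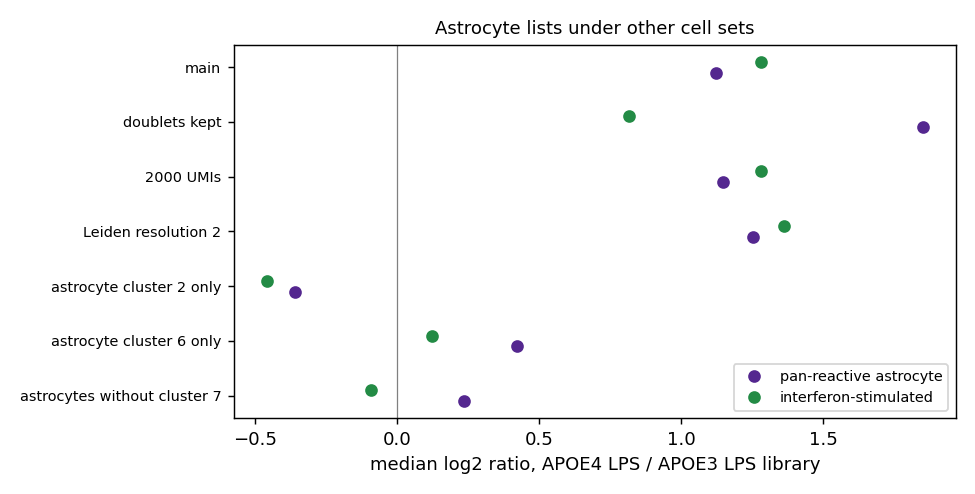
Median log2 ratio of CPM + 1 (APOE4 over APOE3, after LPS) of the pan-reactive and interferon-stimulated lists in astrocytes, for the cells as analysed and for 6 other choices of cells. The pan-reactive median lies at 1.12 as analysed and 1.85 with doublets kept, and at 0.24 without cluster 7.

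The title of the series concerns astrocyte heterogeneity, so single astrocytes were compared at an equal depth of 1000 UMIs. A UMI of Lcn2 was found in 15.3% of APOE4 LPS astrocytes (13.9 to 16.8) and 5.07% of APOE3 LPS astrocytes, against 0 of 4179 in APOE3 NaCl, which allows a share of cells with a UMI of up to 0.0718% (3 counts of the total). Gfap was found in 23.1% of APOE4 LPS (21.4 to 24.8), 16.5% of APOE3 LPS, 3.35% of APOE4 NaCl and 5.89% of APOE3 NaCl astrocytes, and Serpina3n in 31.4%, 20.1%, 4.76% and 0.838%. Gbp2 was found in 10.5% of APOE4 LPS (9.29 to 11.9) and 0.653% of APOE3 LPS astrocytes, Iigp1 in 7.54% and 0.436%, and Cxcl10 in 7.23% and 0.560%. Before thinning, the shares in APOE4 LPS and APOE3 LPS were 23.2% and 11.9% for Lcn2, 42.7% and 37.8% for Gfap, 51.8% and 45.9% for Serpina3n, 21.2% and 2.27% for Gbp2, 14.6% and 1.21% for Iigp1 and 12.9% and 0.964% for Cxcl10, at median depths of 3535 and 3774 UMIs.

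As a background, oligodendrocytes, at median depths of 5402 UMIs in APOE4 LPS and 6045 in APOE3 LPS, had a UMI at equal depth of Lcn2 in 3.30% and 1.57%, Gfap in 1.35% and 1.57%, Gbp2 in 1.13% and 0.0748%, Iigp1 in 0.525% and 0.0374% and Cxcl10 in 0.450% and 0.187%. For Serpina3n, which oligodendrocytes express, microglia (7199 and 7363 UMIs) had 1.10% and 0.329%. The median Fano factor, the variance over the mean, of 1581 genes was 1.07 in APOE3 NaCl, 1.07 in APOE3 LPS, 1.07 in APOE4 NaCl and 1.08 in APOE4 LPS, and its 95th percentile 1.40, 1.45, 1.42 and 1.495. The median correlation between pairs of astrocytes was 0.367, 0.379, 0.372 and 0.362. With a gene floor of 0.5 UMI the median Fano factor was 1.30, 1.29, 1.28 and 1.34.

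**Figure D3:**
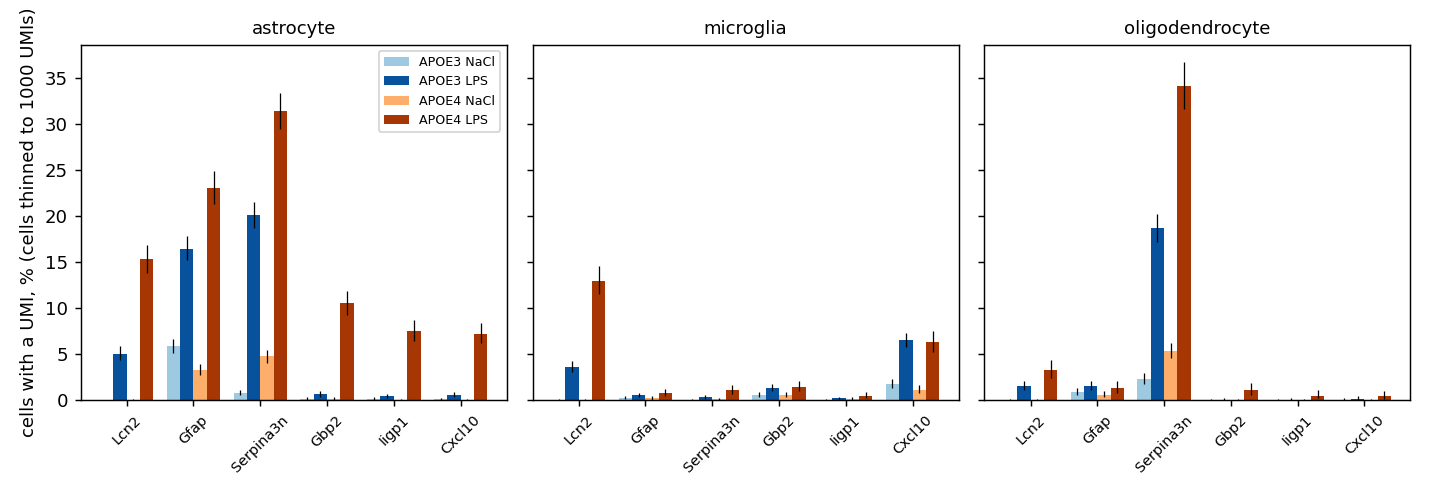
Percent of astrocytes, microglia and oligodendrocytes (panels) with at least 1 UMI of 6 genes after thinning each cell to 1000 UMIs, for the 4 libraries; error bars are exact binomial 95% intervals. Gbp2, Iigp1 and Cxcl10 reach 7.23% to 10.5% of APOE4 LPS astrocytes and under 1% of APOE3 LPS astrocytes.

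In microglia of APOE3 mice, LPS was accompanied by lower homeostatic genes and higher inflammatory genes. NaCl microglia (3185 cells, 14662406 UMIs) lay mostly in clusters 3 and 8, and LPS microglia (4251 cells, 34028969 UMIs) mostly in clusters 4 and 15, the latter led by Tnf, Il1b, Il1a and Ccl4. The homeostatic list had 15 of 17 members lower and 0 higher (median -0.95), with Gpr34 (ENSMUSG00000040229), a receptor of lysophosphatidylserine, at 6.47-fold and the purinergic receptor P2ry12 (ENSMUSG00000036353) at 3.59-fold lower. Marco, a scavenger receptor, had 0 UMIs in NaCl and 1923 in LPS, at least 276-fold higher, the chemokine Ccl5 was 220-fold higher (165 to 301), Plet1 221-fold from 3 UMIs (75.5 to 1074), Ifi207 57.3-fold and the xanthine oxidase gene Xdh 60.9-fold. Lower were the adenylate cyclase Adcy8 at 19.2-fold, Upk1b at 13.4-fold, the clock-related factor Hlf and Tnfrsf17 at 13.6-fold each and Adamts16 at 11.02-fold. Interferon-stimulated genes were higher in 26 of 28 (1.57), with Ifitm3 at 18.5-fold and Zbp1 at 19.8-fold, NF-kB genes in 19 of 21 (1.10), with Bcl3 at 5.83-fold and Saa3 at 935-fold (508 to 1950), and chemokines and cytokines in 16 of 25 with 3 lower (1.13), with Cxcl13 at 335-fold from 1 UMI (60.0 to 13260). Ifitm3, Saa3 and Cxcl13 were at 6.33%, 2.61% and 3.45% of another class's CPM. Apoe counts were 3.33-fold (2.83 to 3.93) and C3 9.22-fold higher, Lcn2 went from 1 to 1790 UMIs, Gfap and Serpina3n were at 1.41% and 0.166% of another class, and Xist had at most 3 UMIs.

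APOE4 microglia (2895 NaCl cells with 13744941 UMIs, 1915 LPS cells with 15574551 UMIs, the latter with 549 in cluster 4 and 1151 in cluster 15, against 2223 and 1917 in APOE3 LPS) also had lower homeostatic and higher inflammatory lists in the LPS library. The homeostatic list was lower in 17 of 17 (-1.29; -0.85, -0.84 and -0.84 at 2000 UMIs, a 10% mitochondrial limit and Leiden resolution 2), with Gpr34 at 8.47-fold and P2ry12 at 4.05-fold lower. Saa3 went from 4 to 95456 UMIs (6129 CPM), the scavenger receptors Msr1 and Marco were 314-fold (203 to 514) and at least 828-fold higher, Ccl5 247-fold (213 to 287) and Mcemp1 at least 200-fold. Tnfrsf17 was 25.0-fold, Adcy8 19.8-fold, the calcitonin receptor modifier Ramp1 10.9-fold and Upk1b 10.6-fold lower. Interferon-stimulated genes were higher in 24 of 29 (1.17), with Zbp1 at 24.0-fold and Ifitm3 at 12.3-fold, NF-kB genes in 17 of 21 (1.29), with Sod2 at 7.39-fold, and chemokines in 16 of 25 with 4 lower (1.05), with Il1rn, the interleukin-1 receptor antagonist, at 390-fold from 1 UMI (69.7 to 15440). Apoe counts were 5.40-fold higher (4.49 to 6.54), and C3 and Lcn2 had 1 and 3 UMIs in NaCl. At Leiden resolution 2, 707 of these LPS cells had no name. There the log2 genotype ratio after LPS was -0.057 for Saa3, -1.15 for Ccl5, -0.62 for Il1rn and -0.23 for Sod2. The LPS folds of these genes may thus rest partly on such cells. Ribosomal protein genes were higher in 52 of 77 with 1 lower (0.73; in APOE3 45 of 77, 0.63), nuclear OXPHOS in 49 of 77 with 1 lower (0.63; in APOE3 19 with 1 lower, 0.44), and glycolysis in 9 of 24 with 3 lower (0.34; in APOE3 7 with 4 lower, 0.23). MHC class I had medians of 0.49 in APOE3 and 0.16 in APOE4, MHC class II -0.22 and -0.27, disease-associated microglia -0.02 and -0.08, and glucocorticoid-responsive genes 0.86 and 1.01, the first turning to -0.14 when possible free-RNA genes were left out. TMM scaling moved the median log2 LPS ratio of all microglial genes by 0.23 in APOE3 and 0.19 in APOE4. The homeostatic medians were then -0.71 and -1.09, and those of disease-associated microglia 0.23 and 0.10.

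Between genotypes in NaCl, microglia had higher C5ar2 in APOE4, a complement receptor, at 5.37-fold (4.40 to 6.60), Spp1 at 4.09-fold (3.31 to 5.10), the scaffold gene Mpp7 at 2.49-fold, Egr3 at 2.19-fold and Eif2s3y at 1.62-fold. The chemokine Ccl12 was 2.76-fold, the receptors Pirb and Fcgr4 2.69-fold and 2.35-fold, Tcim 1.98-fold and the protease Adamts1 1.69-fold lower. List medians were small, at 0.04 for homeostatic, 0.10 for interferon-stimulated (2 of 28 higher, 1 lower), -0.11 for NF-kB, 0.07 for chemokines, 0.03 for disease-associated, 0.12 for MHC class I and -0.38 for MHC class II genes. Gpr34 was 1.25-fold and P2ry12 1.14-fold higher, Isg15 1.66-fold and Ifi27 1.22-fold higher, Tnfaip2 1.21-fold and Socs3 1.11-fold lower, Cxcl9 52.8-fold higher from 2 UMIs (14.2 to 442) and Ccl7 48.8-fold lower with 1 UMI against 52.

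After LPS, microglia had higher Wfdc21 in APOE4 (22.7-fold, 17.4 to 30.2), Fpr1 (16.2-fold), Adam8 (12.1-fold), Saa3 (9.61-fold) and S100a8 (7.47-fold). Wfdc21 and S100a8 also led the neutrophil cluster, whose RNA was not excluded. Il12b was 4.60-fold, Plet1 3.19-fold, Oasl2 2.34-fold, Tnfsf13 1.96-fold and Cyp4f18 1.94-fold lower. The homeostatic median was -0.25, with Selplg at 1.33-fold and Sparc at 1.30-fold lower. The interferon median was -0.14 (1 of 29 higher, 2 lower, percentile 1.31), with Ifit3 at 1.84-fold lower, and NF-kB was at 0.06, chemokines at 0.05, nuclear OXPHOS at 0.26, ribosomal protein genes at 0.10, glucocorticoid at 0.22, MHC class I at -0.18 and MHC class II at -0.52. Much of this depended on which cells entered the class. In the 4 settings that follow, 675, 664, 709 and 707 APOE4 LPS cells of this class, with median depths of 10402 to 10540 UMIs, lay in clusters without a name. With doublets kept, at 2000 UMIs, at a 10% mitochondrial limit and at Leiden resolution 2, the homeostatic median was 0.18, 0.18, 0.19 and 0.18, the OXPHOS, ribosomal and glucocorticoid medians lay below 0 (-0.20 to -0.0074), and Sod2 (2.26-fold as analysed), Ccl5 (4.63-fold), Il1rn (4.47-fold), C3 (1.57-fold) and Apoe counts (1.36-fold) were lower in APOE4 in all 4. At Leiden resolution 2 Saa3 had a log2 ratio of -0.057, and at the 10% limit S100a8 one of -0.075. MHC class II turned to 0.094 with cluster 19 counted as microglia.

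In endothelial cells, which line the vessels and meet circulating LPS, the APOE3 LPS library (818 cells, 6066795 UMIs, mostly cluster 5) was compared with the NaCl library (853 cells, 4346173 UMIs, mostly cluster 9). Of the endothelial activation genes 14 of 15 were higher and 0 lower (median 3.48). Lcn2 was 527-fold higher (357 to 814), at 3029 CPM, and the atypical chemokine receptor Ackr1 175-fold (80.1 to 477). The cytokine Csf3 (ENSMUSG00000038067) had 0 and 416 UMIs, at least 99.3-fold, and Tnfsf8 and the activin subunit Inhbb were 703-fold and 368-fold higher from 1 UMI each (126 to 27790 and 65.7 to 14540). Barrier genes were lower in 10 of 16 with 0 higher (-1.11), with Spock2 at 8.69-fold and the amino acid transporter Slc7a5 at 4.95-fold lower. Gkn3 was 48.4-fold, Fbln2 40.7-fold, Scube2 28.2-fold, Unc13c 25.1-fold and the organic anion transporter Slc22a8 22.7-fold lower. NF-kB genes were higher in 20 of 21 (1.73) and interferon-stimulated genes in 6 of 29 with 3 lower (0.09). TMM scaling moved the median log2 ratio of all genes by 0.11 here.

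In APOE4 endothelial cells (605 NaCl cells with 2423265 UMIs, 401 LPS cells with 2322862 UMIs, same clusters) 16 of 17 activation genes were higher (3.57), 13 of 16 barrier genes lower (-1.17), 19 of 21 NF-kB genes higher (1.38) and 7 of 29 interferon-stimulated genes higher with 1 lower (0.23). Csf3 was at least 329-fold and Tnfsf8 at least 219-fold higher, the protease Adamts9 200-fold (133 to 316), Lcn2 91.4-fold (78.1 to 108) and Ccl5 1153-fold from 1 UMI (207 to 45570). Gkn3 was 44.97-fold, Akr1c14 21.7-fold, Dbp 12.5-fold, Slc22a8 11.3-fold, Itm2a 9.07-fold, Spock2 7.10-fold and the glutamine transporter Slc38a5 5.86-fold lower. Transcripts of other cells were higher in this library too: homeostatic astrocyte genes in 17 of 19 (2.15, against -0.19 in APOE3), myelin genes in 9 of 12 (0.75, against -0.88) and the microglial monitor list (3.22, against 2.35). Interferon-stimulated genes turned to -0.072 with filters of 200 genes and 500 UMIs, and myelin genes to -3.96 with doublets kept, -1.34 at 2000 UMIs and -0.36 with cells that held markers of another class removed. With a pseudocount of 10 the activation medians were 2.23 in APOE3 and 2.36 in APOE4.

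Between genotypes in NaCl, endothelial cells of APOE4 had higher Lcn2 (11.3-fold, 7.40 to 18.1), Ackr1 (14.7-fold), Ptgs2, the inducible prostaglandin synthase (4.99-fold), Lrg1 (3.68-fold) and the adhesion molecule Vcam1 (2.11-fold), and lower Apln (185-fold with 1 UMI against 331, bounds of the ratio 0.000137 to 0.0304), the angiopoietin Angpt2 (11.5-fold), Adamts9 (7.27-fold), the haemoglobin gene Hbb-bs (6.46-fold) and the cyclin Ccnd1 (4.27-fold). Hbb-bs turned to a log2 ratio of 0.96 with doublets kept. Activation genes were higher in 7 of 13 with 3 lower (1.07), including the selectin Sele at 28.7-fold from 2 UMIs (7.32 to 247), and their median was 0.42 with no low-count filter, 0.43 by the mean of each cell's CPM, and 0.51 both from 50 UMIs and with a pseudocount of 10. Barrier genes were near 0 (0.07), with Abcg2 at 1.195-fold and Slc38a5 at 1.32-fold. After LPS the activation median was 0.67, with 9 of 17 higher, Selp 11.9-fold higher (8.10 to 17.9) and Il6 at least 13.9-fold. It was -0.12 with filters of 200 genes and 500 UMIs, -0.070 at Leiden resolution 2, 0.098 at a 10% mitochondrial limit and 0.40 measured from 50 UMIs. Barrier genes were at -0.15, with Slco1a4 at 1.37-fold and Ocln at 1.44-fold lower.

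Also higher in APOE4 LPS endothelial cells were genes of other cells, namely the macrophage receptors Marco (159-fold from 1 UMI, 27.5 to 6395) and Msr1 (17.99-fold), the chemokines Ccl5 (28.0-fold) and Cxcl13 (48.8-fold from 3 UMIs, 15.9 to 244), the astrocyte genes Gpc5 (12.3-fold) and Aqp4 (8.83-fold), the myelin gene Ermn (16.2-fold) and the microglial C1qb (2.12-fold) and Ctss (2.13-fold). Haemoglobin genes were lower, with Hbb-bs at 7.43-fold, Hba-a1 at 5.24-fold, Hba-a2 at 4.66-fold and Hbb-bt at 5.16-fold, as was Fam78b at 2.45-fold. Gpc5 turned to a log2 ratio of -0.33 when cells with markers of another class were removed. Serpina3n was 1.42-fold and Lcn2 1.97-fold higher, but Serpina3n turned to -0.33 with doublets kept and -0.54 without cells with markers of another class, and Hba-a2 to 0.032 by the mean of each cell's CPM.

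Across genes, the LPS effects of the genotypes, which share no library, were correlated in astrocytes (Pearson r 0.606, Spearman rho 0.463, 16236 genes), microglia (0.842 and 0.773, 15412 genes) and endothelial cells (0.679 and 0.619, 12984 genes). Of 435 genes that differed at least 2-fold in APOE3 astrocytes, 92.6% had the same direction in APOE4, as did 98.7% of 1081 in microglia and 89.8% of 1779 in endothelial cells. The genotype difference in NaCl was not carried over to LPS in the same way, with an r of -0.031, 0.0764 and 0.0037 and a rho of 0.0108, 0.0488 and 0.0572. Of 64 genes with a 2-fold genotype difference in NaCl astrocytes 39.1% had the same direction after LPS, of 59 in microglia 61.0% and of 382 in endothelial cells 49.0%. These are 6 relations across genes, and genes are not independent replicates.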

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

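For the results below, the tests of free RNA, doublets by mixed markers, leaving out cluster 7, pooled mice, empty droplets and intact cells were chosen only after the result was seen, and that of cluster 19 after the data but before its own result was seen. The log2 effect of LPS lay in opposite directions in APOE3 and APOE4, at 0.5 or more from 0 in both, for 13 results among 111 lists and 227 genes, and these differences were not tested, since each group is 1 library. In astrocytes the log2 LPS ratio of APOE4 minus that of APOE3 was 4.23 for Cd44 (-0.88 in APOE3 and 3.36 in APOE4), 3.36 for Clcf1, a cytokine (-0.67 and 2.69), 2.93 for Gadd45b (-0.93 and 2.003), 5.02 for Ptx3 (-0.86 and 4.16) and 3.31 for Tgm1, a transglutaminase (-0.53 and 2.79). In microglia it was -2.56 for Spp1, the osteopontin gene (1.98 and -0.58). In endothelial cells it was 3.96 for the MHC class II list (-0.85 over 6 members and 3.11 over 3, in libraries where the microglial monitor list was at 2.35 and 3.22; the median difference over the same 6 members was 1.21), 1.63 for myelin genes (-0.88 and 0.75), 5.21 for Apln (-1.78 and 3.43), 3.48 for the water channel gene Aqp4 (-0.74 and 2.74), 2.54 for Ccnd1 (-1.19 and 1.36), 2.81 for Ermn (-1.98 and 0.82) and 5.37 for Gpc5 (-1.80 and 3.57). Called doublets were removed from the other libraries and none from APOE4 LPS, and the LPS ratio of myelin genes in APOE4 endothelial cells turned to -3.96 with doublets kept in all libraries and to -0.36 with mixed-marker cells removed. The endothelial ratio of APOE4 to APOE3 after LPS turned to -0.33 for Gpc5 with mixed-marker cells removed. The astrocyte difference of Cd44 turned to -0.42 without cluster 7.

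Interferon-stimulated and reactive genes were higher in APOE4 LPS than APOE3 LPS astrocytes (interferon median 1.28), but without cluster 7, which came mostly from the APOE4 LPS library and is defined in part by such genes, the interferon median was -0.091. The tables argue against free RNA as the whole cause, since the excess of the summed interferon list over APOE3 LPS in oligodendrocytes was 40.9% of that in astrocytes (304 against 743 CPM), although a value under 50% was set as the limit after related values had been seen. Depth stays open. The interferon median was 1.28 in cells of at least 2000 UMIs, but these held 8308676 UMIs in APOE4 LPS astrocytes, against 9092970 as analysed. Doublets with microglia stay open, since removing mixed-marker cells (1.43) took only 73 of 2281 in APOE4 LPS. That some of the 3 pooled mice responded more than others stays open, since the lowest share over 11 classes of APOE4 LPS cells above the APOE3 LPS 95th percentile of Mt1 was 12.4% and the highest 44.1%, but the mean of the cells with the lowest Mt1 (up to the median) was also higher in all 11. Pool and batch cannot be told apart from genotype, so a genotype difference stays untested.

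Clusters without a name held 43.7% of APOE4 LPS cells, at a median of 1636 UMIs, of which 62.1% were under 2000 UMIs, and with a filter of 2000 UMIs 37.4% of cells had no name (3790, of which 2518 had none as analysed either). Part of them may be free RNA in empty droplets, and the profile of all of them correlated across genes with that of barcodes under 1000 UMIs (0.978), but the erythroid class, itself of low-UMI barcodes with a median of 1383 UMIs, did so slightly better (0.980), ahead of the next class (0.906). They could also be intact cells of 1 class sequenced less deeply, and 0 of the 3 such clusters led by APOE4 LPS had the markers of a class, which decides nothing because clusters with enough markers were named. Both readings were first counted against the explanations and changed to open after those values had been seen. No biological explanation was tested.

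In APOE4 LPS against APOE3 LPS, interferon-stimulated genes had a median of 1.28 in astrocytes (23 of 28 at least 1.5-fold higher; -0.091 without cluster 7, so the contrast rests on that cluster) and of -0.14 in microglia, where 1 of 29 was higher, 2 were lower and the rest lay within 1.5-fold. Microglia left unnamed in cluster 19 do not account for the lower median in microglia, since the microglia median was -0.22 with that cluster included. Free RNA stays open, since the microglia median was -0.25 and that of astrocytes 1.33 after subtraction with an assumed profile, which excludes nothing. A difference by genotype between the classes stays open and untested.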

How the results depend on the processing

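The alternatives of single clusters, no cluster 7, cluster 19 as microglia, free RNA subtracted, mixed-marker cells removed and the correlation floor of 200 UMIs were tests chosen only after the data had been seen. No paired analysis was possible because the groups share only replicate number 1 and no test was made. Of 7756 values recomputed under the alternatives, 5698 stayed within their counting interval, 1928 moved beyond it and 130 turned sign. A turn was counted for a gene or correlation whose interval left out 0 and for a list outside the central 95% of random lists, and 99 other values also changed sign. Under the alternatives fixed in advance these numbers were 4663, 1301 and 68 of 6032, and under those chosen later 1035, 627 and 62 of 1724. The set of values was narrowed after a first and wider run, in which 236 of 9938 turned sign (132 of 7549 and 104 of 2389), had been seen. Counting intervals are narrow at these depths and omit variation between cells and mice, so a value beyond its interval can be a small move. A list is named by its genes and its value is the median of its members. The values below are log2 ratios unless named otherwise, and the cause was not tested for any of them except where the alternative leaves out the cells or genes that carry the value. For comparison, the values as analysed were 1.05, 3.36, -0.99 and 1.12 for the pan-reactive list in astrocytes and 2.10 for its difference of LPS effects, -0.95, -1.29, 0.04 and -0.25 for homeostatic genes in microglia and 3.48, 3.57, 1.07 and 0.67 for activation genes in endothelial cells, in the order LPS in APOE3, LPS in APOE4, genotype in NaCl and genotype after LPS.

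With doublets kept, across genes in astrocytes the correlation of LPS effects was 0.704 and the correlation of genotype differences was -0.00722. With doublets kept, the median Fano factor was 1.08 for APOE3 LPS, 1.07 for APOE3 NaCl, 1.08 for APOE4 LPS and 1.07 for APOE4 NaCl. With doublets kept, the astrocyte share in percent was 13.9 for APOE4 LPS. With doublets kept, in astrocytes the genotype ratio after LPS was 1.85 for pan-reactive genes, the genotype ratio in NaCl was -0.77 for pan-reactive genes and turned to 0.028 for Col23a1, the LPS ratio in APOE3 turned to 0.36 for A2 genes and -0.18 for homeostatic microglial genes, and the LPS ratio in APOE4 turned to -0.26 for homeostatic microglial genes. With doublets kept, in endothelial cells the genotype ratio after LPS turned to -0.33 for Serpina3n, the genotype ratio in NaCl turned to 0.96 for Hbb-bs and -0.023 for interferon genes, and the LPS ratio in APOE4 turned to -3.96 for myelin. With doublets kept, in microglia the genotype ratio after LPS turned to -0.64 for Apoe, -1.05 for C3, -0.56 for Ccl5, -0.66 for Il1rn, -0.0074 for nuclear OXPHOS, 0.16 for Selplg, -0.088 for Sod2, -0.16 for ribosomal proteins, -0.15 for glucocorticoid genes and 0.18 for homeostatic microglial genes, the LPS ratio in APOE3 was -0.94 for homeostatic microglial genes, and the LPS ratio in APOE4 was -0.86 for homeostatic microglial genes. With filters of 200 genes and 500 UMIs, across genes in astrocytes the correlation of LPS effects was 0.600. With these filters, the astrocyte share in percent was 8.47 for APOE4 LPS and 29.2 for APOE4 NaCl. With filters of 200 genes and 500 UMIs, in endothelial cells the genotype ratio after LPS turned to -0.10 for NF-kB genes and -0.12 for endothelial activation, and the LPS ratio in APOE4 was 3.00 for endothelial activation and turned to -0.072 for interferon genes. With these filters, homeostatic microglial genes in microglia had ratios of -0.38 for genotype after LPS and -1.45 for LPS in APOE4. At 2000 UMIs, across genes in astrocytes the correlation of LPS effects was 0.552 and the correlation of genotype differences was -0.0748. At 2000 UMIs, the median Fano factor was 1.07 for APOE3 LPS, 1.07 for APOE3 NaCl, 1.07 for APOE4 LPS and 1.06 for APOE4 NaCl. At 2000 UMIs, the astrocyte share in percent was 22.4 for APOE3 LPS and 17.9 for APOE4 LPS. At 2000 UMIs, in endothelial cells the LPS ratio in APOE4 turned to -1.34 for myelin. At 2000 UMIs, in microglia the genotype ratio after LPS turned to -0.64 for Apoe, -0.78 for C3, -0.55 for Ccl5, -0.68 for Il1rn, -0.029 for nuclear OXPHOS, 0.17 for Selplg, -0.19 for Sod2, -0.19 for ribosomal proteins, -0.18 for glucocorticoid genes and 0.18 for homeostatic microglial genes, the LPS ratio in APOE3 was -0.94 for homeostatic microglial genes, and the LPS ratio in APOE4 was -0.85 for homeostatic microglial genes. At a 10% mitochondrial limit, across genes in astrocytes the correlation of LPS effects was 0.576 and the correlation of genotype differences was -0.0403. At this limit, the median Fano factor was 1.07 for APOE3 NaCl and 1.07 for APOE4 LPS. At a 10% mitochondrial limit, in endothelial cells the genotype ratio after LPS was 0.098 for endothelial activation and turned to -0.0040 for NF-kB genes, and the LPS ratio in APOE4 was 3.15 for endothelial activation. At a 10% mitochondrial limit, in microglia the genotype ratio after LPS turned to -0.80 for Apoe, -1.07 for C3, -0.87 for Ccl5, -0.64 for Il1rn, -0.031 for nuclear OXPHOS, -0.075 for S100a8, 0.19 for Selplg, -0.26 for Sod2, -0.20 for ribosomal proteins, -0.18 for glucocorticoid genes and 0.19 for homeostatic microglial genes, the LPS ratio in APOE3 was -0.93 for homeostatic microglial genes, and the LPS ratio in APOE4 was -0.84 for homeostatic microglial genes. At Leiden resolution 2, across genes in astrocytes the correlation of LPS effects was 0.566 and the correlation of genotype differences was -0.0575. At Leiden resolution 2, the astrocyte share in percent was 18.1 for APOE3 LPS, 21.5 for APOE3 NaCl, 10.4 for APOE4 LPS and 17.5 for APOE4 NaCl. At Leiden resolution 2, in astrocytes the genotype ratio after LPS turned to 0.74 for Crym, the LPS ratio in APOE3 turned to 0.26 for A2 genes, and the LPS ratio in APOE4 was 3.65 for pan-reactive genes. At Leiden resolution 2, in endothelial cells the genotype ratio after LPS turned to -0.073 for NF-kB genes and -0.070 for endothelial activation, the genotype ratio in NaCl turned to 0.033 for astrocyte homeostatic, and the LPS ratio in APOE4 was 3.01 for endothelial activation. At Leiden resolution 2, in microglia the genotype ratio after LPS turned to -0.76 for Apoe, -1.19 for C3, -1.15 for Ccl5, -0.62 for Il1rn, -0.024 for nuclear OXPHOS, -0.057 for Saa3, 0.18 for Selplg, -0.23 for Sod2, -0.18 for ribosomal proteins, -0.18 for glucocorticoid genes and 0.18 for homeostatic microglial genes, the LPS ratio in APOE3 was -0.94 for homeostatic microglial genes, and the LPS ratio in APOE4 was -0.84 for homeostatic microglial genes. With TMM factors, across genes in astrocytes the correlation of LPS effects was 0.600 and the correlation of genotype differences was -0.0369. With TMM factors, in astrocytes the genotype ratio after LPS was 1.07 for pan-reactive genes. With TMM factors, homeostatic microglial genes in microglia had a genotype ratio of -0.27 after LPS and 0.064 in NaCl. Their LPS ratio was -0.71 in APOE3 and -1.09 in APOE4. Without mitochondrial and top 20 genes, across genes in astrocytes the correlation of LPS effects was 0.601. Without mitochondrial and top 20 genes, homeostatic microglial genes in microglia had ratios of 0.052 for genotype in NaCl and -1.32 for LPS in APOE4. By the mean of each cell's CPM, across genes in astrocytes the correlation of LPS effects was 0.576 and the correlation of genotype differences turned to 0.0200. By this mean, pan-reactive genes in astrocytes had a genotype ratio in NaCl of -0.74. Their LPS ratio in APOE3 was 1.39 and the difference of LPS effects was 1.68. By the mean of each cell's CPM, in endothelial cells the genotype ratio after LPS was 0.47 for endothelial activation and turned to 0.032 for Hba-a2, the genotype ratio in NaCl was 0.43 for endothelial activation, and the LPS ratio in APOE4 was 4.18 for endothelial activation. By this mean, homeostatic microglial genes in microglia had a genotype ratio after LPS of -0.15. Their LPS ratio was -0.94 in APOE3 and -1.11 in APOE4. With a pseudocount of 10, across genes in astrocytes the correlation of LPS effects was 0.654 and the correlation of genotype differences was -0.00917. With a pseudocount of 10, pan-reactive genes in astrocytes had a genotype ratio in NaCl of -0.32. Their LPS ratio was 0.61 in APOE3 and 2.71 in APOE4, and the difference of LPS effects was 1.93. With a pseudocount of 10, endothelial activation in endothelial cells had a genotype ratio in NaCl of 0.51. Its LPS ratio was 2.23 in APOE3 and 2.36 in APOE4. Measuring from 50 UMIs, across genes in astrocytes the correlation of LPS effects was 0.652 and the correlation of genotype differences was -0.0678. Measuring from 50 UMIs, in astrocytes the genotype ratio after LPS was 2.48 for pan-reactive genes, and the LPS ratio in APOE3 turned to 0.60 for A2 genes. Measuring from 50 UMIs, endothelial activation in endothelial cells had a genotype ratio of 0.40 after LPS and 0.51 in NaCl. Its LPS ratio in APOE3 was 4.15. With no low-count filter, across genes in astrocytes the correlation of LPS effects was 0.572. With no low-count filter, in astrocytes the LPS ratio in APOE3 turned to 0.16 for A2 genes. With no low-count filter, endothelial activation in endothelial cells had ratios of 0.42 for genotype in NaCl and 2.93 for LPS in APOE3. Leaving out possible free-RNA genes, across genes in astrocytes the correlation of LPS effects was 0.596. Leaving out possible free-RNA genes, in astrocytes the genotype ratio after LPS was 2.52 for pan-reactive genes, the genotype ratio in NaCl was -0.76 for pan-reactive genes, the LPS ratio in APOE3 turned to -0.0013 for disease-associated microglia and -0.24 for endothelial activation, the LPS ratio in APOE4 was 3.73 for pan-reactive genes and turned to -0.23 for chemokines, and the difference of LPS effects was 3.03 for pan-reactive genes. Leaving out possible free-RNA genes, in microglia the LPS ratio in APOE3 turned to -0.14 for glucocorticoid genes. Thinned to 2000 UMIs, the median Fano factor was 1.08 for APOE3 LPS, 1.08 for APOE3 NaCl, 1.09 for APOE4 LPS and 1.08 for APOE4 NaCl. With a gene floor of 0.5 UMI, the median Fano factor was 1.29 for APOE3 LPS, 1.30 for APOE3 NaCl, 1.34 for APOE4 LPS and 1.28 for APOE4 NaCl.

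In cluster 2, in astrocytes the genotype ratio after LPS turned to -0.080 for A1 genes, -1.13 for Bcl3, -1.19 for Gfap, -0.50 for Hk2, -0.64 for Isg15, -0.043 for Lcn2, -0.21 for MHC class I, -0.77 for Map3k6, -0.023 for Msmo1, -0.16 for NF-kB genes, -0.78 for Serpina3n, -0.036 for disease-associated astrocyte, -0.070 for glucocorticoid genes, -0.46 for interferon genes and -0.36 for pan-reactive genes, the genotype ratio in NaCl was -0.36 for pan-reactive genes and turned to 0.0087 for Col23a1 and 0.014 for Fbln5, the LPS ratio in APOE3 was 0.86 for pan-reactive genes, the LPS ratio in APOE4 was 1.02 for pan-reactive genes and turned to -0.067 for Mt2, and the difference of LPS effects turned to -0.35 for Cd44, -0.21 for Lcn2, -0.40 for interferon genes and -0.00065 for pan-reactive genes. In cluster 6, in astrocytes the genotype ratio after LPS was 0.42 for pan-reactive genes and turned to -0.51 for Gfap, -0.30 for Lcn2, -0.029 for Map3k6, -0.094 for Serpina3n and -0.13 for glucocorticoid genes, the genotype ratio in NaCl turned to 0.066 for A2 genes, 0.12 for Col23a1, 0.078 for Gfap, -0.055 for Naaa, -0.034 for Ppp1r3g, 0.047 for S100a10 and 0.16 for pan-reactive genes, the LPS ratio in APOE3 was 1.86 for pan-reactive genes and turned to 0.75 for A2 genes and 0.025 for Col23a1, the LPS ratio in APOE4 was 1.80 for pan-reactive genes and turned to 0.52 for Chrdl1, and the difference of LPS effects was 0.069 for pan-reactive genes and turned to -0.28 for Cd44, -0.59 for Gfap and -0.12 for Lcn2. Without cluster 7, in astrocytes the genotype ratio after LPS was 0.24 for pan-reactive genes and turned to -0.80 for Gfap, -0.19 for Lcn2, -0.058 for MHC class I, -0.41 for Map3k6, -0.26 for Serpina3n, -0.038 for disease-associated astrocyte, -0.15 for glucocorticoid genes and -0.091 for interferon genes, the genotype ratio in NaCl was -0.11 for pan-reactive genes and turned to 0.063 for Col23a1, the LPS ratio in APOE3 turned to 0.41 for A2 genes, the LPS ratio in APOE4 was 1.54 for pan-reactive genes, and the difference of LPS effects was 0.15 for pan-reactive genes and turned to -0.42 for Cd44 and -0.19 for Lcn2. With cluster 19 as microglia, in microglia the genotype ratio after LPS was -0.57 for homeostatic microglial genes and turned to 0.094 for MHC class II, and the LPS ratio in APOE4 was -1.65 for homeostatic microglial genes. With free RNA subtracted, across genes in astrocytes the correlation of LPS effects was 0.599. With free RNA subtracted, in astrocytes the genotype ratio after LPS was 2.54 for pan-reactive genes, the genotype ratio in NaCl was -1.59 for pan-reactive genes, the LPS ratio in APOE3 was 1.61 for pan-reactive genes and turned to -0.042 for endothelial activation and 1.21 for myelin, and the difference of LPS effects was 3.00 for pan-reactive genes. With free RNA subtracted, in endothelial cells the genotype ratio in NaCl was 1.34 for endothelial activation, and the LPS ratio in APOE3 turned to 1.83 for myelin. With free RNA subtracted, in microglia the genotype ratio after LPS was -0.21 for homeostatic microglial genes and turned to -0.43 for Serpina3n. The LPS ratio of the homeostatic genes was -1.03 in APOE3 and -1.33 in APOE4. With mixed-marker cells removed, across genes in astrocytes the correlation of LPS effects was 0.570. With mixed-marker cells removed, in astrocytes the LPS ratio in APOE3 turned to -0.024 for homeostatic microglial genes. With mixed-marker cells removed, in endothelial cells the genotype ratio after LPS turned to -0.33 for Gpc5 and -0.54 for Serpina3n, the genotype ratio in NaCl turned to -0.42 for the microglial monitor list, and the LPS ratio in APOE4 was 4.01 for endothelial activation and turned to -0.36 for myelin. With a correlation floor of 200 UMIs, across genes in astrocytes the correlation of LPS effects was 0.668 and the correlation of genotype differences was -0.0834.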

Other observations

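The alternatives with doublets kept and with possible free-RNA genes left out were planned, while the tests with free RNA subtracted and mixed-marker cells removed were chosen only after the data were seen. In astrocytes, chemokines and cytokines had a median log2 LPS ratio of 0.61 in APOE3 (11 of 18 higher, 1 lower) and 1.07 in APOE4 (17 of 22 higher, 1 lower), the latter turning to -0.23 with possible free-RNA genes left out. MHC class II genes, with 4 measured, were at 0.35 and 0.56. Immediate early genes were at 0.19 and 0.68, the latter with 12 of 20 higher and 2 lower, and hypoxia genes at -0.40 and -0.44. Fatty acid oxidation was at 0.15 and 0.01, the tricarboxylic acid cycle at -0.02 and -0.12, mitochondrially encoded OXPHOS at 0.53 and 0.21, ribosomal protein genes at 0.15 and 0.38 and the unfolded protein response at 0.06 and 0.27. Lipoprotein and cholesterol efflux genes were at 0.01 and -0.04, lipid droplet genes at -0.08 and -0.06 and iron handling at 0.01 and 0.06.

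Lists of other cell types were measured in astrocytes too, in the order APOE3 and APOE4. Microglial homeostatic genes were at 0.32 and 0.86, which turned to -0.18 and -0.26 with doublets kept, and the former to -0.024 with mixed-marker cells removed. Disease-associated microglial genes were at 0.18 and 0.52, the former turning to -0.0013 with possible free-RNA genes left out. Endothelial activation genes were at 0.58 and 1.29, the former turning to -0.24 with those genes left out and to -0.042 with free RNA subtracted, and barrier genes were at -0.08 and 0.18. Myelin genes were at -0.34 and -0.17, the former turning to 1.21 with free RNA subtracted. Monitor lists stood at 0.34 and 0.76 for endothelial, 0.12 and -0.20 for neuronal, -0.26 and 0.07 for choroid plexus and -0.94 and -0.27 for erythroid transcripts, and at 1.98 in APOE3 for neutrophil transcripts, of which 3 were measured.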
